A study of Ovis aries with 20 samples.

How the data were processed

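Abomasal lymph node tissue was kept in RNAlater and total RNA was extracted with TRI Reagent, per the labels' protocols. RNA under 200 nucleotides and genomic DNA were removed on columns and by DNase. Libraries were made with the TruSeq RNA v2 kit, which does not mark the strand, with 10 PCR cycles, and sequenced as 50 bp paired-end reads on a HiSeq2000 with each pool on 2 lanes. The authors deposited 1 table per library of raw counts per Ensembl sheep gene identifier, not normalized. Per the submitters' processing notes, the tools were CASAVA 1.8.0, Trim Galore 0.3.3, STAR, HTSeq 0.5.3p3, edgeR 3.0.8 and R 3.0.2. The notes give no role or order for these tools, and the genome build, annotation release and counting settings are not given in the sources used here. The table layout, with rows for reads counted in no gene and ambiguous reads, is that of HTSeq counts. Reads counted in no gene are called reads outside genes here, although some may lie within genes, since the counting settings are not given. Because the kit does not mark the strand, reads of overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies can also lose reads, whatever the kit. Ambiguous reads were 0.684% to 0.814% of each library.

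The tables hold 25197 gene identifiers, of which 21655 had a count in any library, and 5 rows that name no gene. Some of those rows carried commas within the numbers, which were removed. The identifiers were set against a table of 35057 RefSeq genes of assembly ARS-UI_Ramb_v3.0, and 0 matched, since that table holds no Ensembl identifier. No gene symbol was therefore used, and no coordinates are given. The 27 gene lists fixed beforehand, their enrichment tests and the genes to be reported by symbol could not be used, because they are written in symbols. The rule for naming genes, fixed before the data were examined, was the most changed genes past the threshold, filled up with those of smallest p. Without symbols it was reduced to the 2 genes of smallest p in each direction of each comparison, said to pass or not. ENSOARG00000009143, ENSOARG00000008077, ENSOARG00000009526, ENSOARG00000011082 and ENSOARG00000016098, in the closing part, and ENSOARG00000010231 fall outside that rule and were chosen after their values were seen.

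Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 15030 genes. Library sizes were scaled by TMM, and CPM values are TMM-scaled. A model with 1 mean per group over all 20 libraries was fitted with robust dispersion estimates, and contrasts were tested with edgeR's quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors and confidence intervals of log2 fold changes were derived from the F statistic, as the size of the change over its square root, and do not hold for a group with almost no counts. There were 7 contrasts: the 4 pairwise ones, the interaction of phenotype and day, and the 2 contrasts averaged over the other factor. Log2 CPM for correlations between libraries and for principal components used a prior count of 2. Groups came from the phenotype and day labels. Replicates are numbered in accession order, so the numbers pair nothing. Different lambs were sampled at each day. The labels describe lambs but do not state in words that each library came from a separate one, so p-values measure the spread between these libraries. No labels of batch, lane or pool were used, and none entered the model.

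No library was a duplicate of another: the chi-square statistic per degree of freedom of the counts of any pair of libraries was at least 6.93. Library measures were compared by exact two-sided permutation tests of 5 against 5 libraries (252 assignments, smallest possible p 0.0079), adjusted over 16 tests. The share of reads outside genes was added to that family after the data were seen. A limit of 3 counts corresponds to 0.0864 CPM in the deepest library and 0.332 CPM in the shallowest. Ratios of summed counts have exact 95% binomial intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

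The test was checked on simulated data: counts were drawn for the 15030 genes from the real means, library sizes and dispersions, with 50 genes changed by each of 1.5-, 2-, 3- and 4-fold. In the 4 pairwise comparisons 2.53% to 6.67% of the genes called were unchanged ones, and every changed gene that was called had the right direction. Each gene was drawn independently of the others, so these shares do not cover correlation between genes in the real libraries. Alternatives set before the data were examined were DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), edgeR's likelihood ratio test, RLE scaling, no filter, a filter of CPM over 1 in at least 5 libraries, removal of the 20 most abundant genes, a fit to the 10 libraries of the comparison, an adjusted p threshold of 0.1, and leaving out each library in turn. edgeR's exact test was added after the data were seen. Each contrast was also refitted on 100 splits of the libraries, the real one included, phenotype being reassigned within day or day within phenotype.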

Results

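RNA from the abomasal lymph node, which drains the fourth stomach compartment of ruminants, was sequenced from Scottish Blackface lambs (Ovis aries). The lambs had been given 30000 third-stage larvae of Teladorsagia circumcincta, a nematode that lives in the abomasum. The labels give each lamb a phenotype, High_FEC or Low_FEC, where FEC is the usual abbreviation for faecal egg count, a measure of worm burden. Lambs with low counts are the more resistant animals. Nodes were collected 7 or 14 days after infection, which gave 4 groups of 5 libraries. Each library was deposited as read counts for 25197 Ensembl sheep gene identifiers. The total count in genes ranged from 9024996 to 34710314 per library, and between 17544 and 19046 genes had at least 1 count in a library. A further 41.05% to 46.57% of the reads of each library were counted in no gene, though some of them may lie within genes. The files used here pair no identifier with a gene symbol, so genes are given by identifier and nothing is said of their function.

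Libraries of the same group were about as alike as libraries of different groups. The median Pearson correlation of log2 CPM, the counts scaled to library size, was 0.9813 between libraries of the same group (40 pairs) and 0.9809 between libraries of different groups (150 pairs). The lowest correlation was 0.9648 within a group and 0.9721 between groups. The first principal component held 12.6% of the variance and the second 9.55%, and neither separated the 4 groups. Low_FEC day 14 replicates 1 and 3 lay at the opposite ends of the first, at -36.9 and 33.8, so that group was widely spread on it. The biological coefficient of variation was 0.163 for all genes in common. Total counts, detected genes, the share of counts in the 10 most abundant genes and the share of reads outside genes did not differ between groups past the threshold in exact two-sided permutation tests (16 tests, smallest p = 0.06349, Benjamini-Hochberg adjusted p = 0.5714). That smallest p belonged to the number of detected genes in Low_FEC lambs, with 18591 ± 359.9 at day 7 and 18068 ± 424.6 at day 14 (SD, n = 5).

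**Figure D1:**
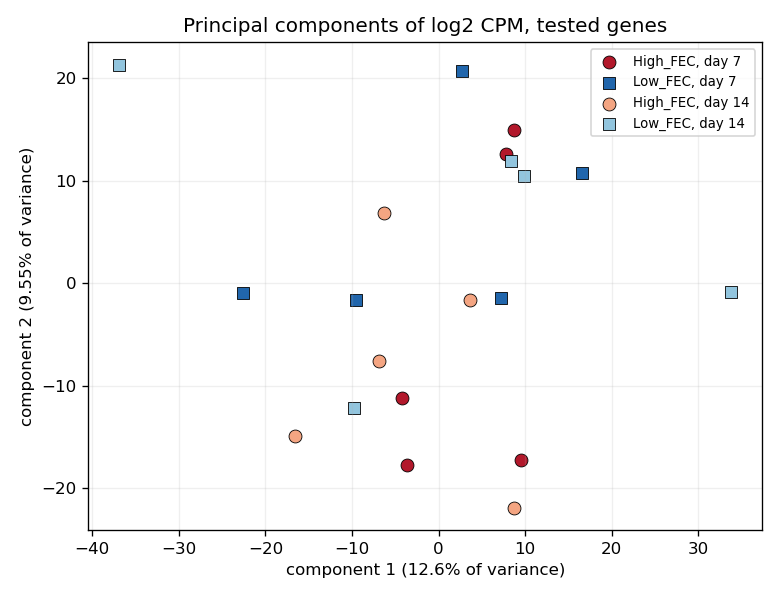
Principal components 1 (12.6% of variance) and 2 (9.55% of variance) of log2 CPM over the 15030 tested genes, with 1 point per library, coloured by phenotype and day. Libraries of the 4 groups are interspersed on both axes, but both ends of component 1 are Low_FEC day 14 libraries, replicate 1 at -36.9 and replicate 3 at 33.8.

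The series asks how lambs that differ in nematode resistance respond at each time, and the phenotype comparison at day 7 addresses the earlier time. ENSOARG00000013782 had the smallest p. It stood at 3.14 ± 1.46 CPM in High_FEC and 0.643 ± 0.387 CPM in Low_FEC lambs (SD, n = 5), and every High_FEC library (1.71 to 5.22 CPM) lay above every Low_FEC library (0.0784 to 1.15 CPM). Its log2 fold change, Low_FEC minus High_FEC, was -2.18 (SE 0.393), with an edgeR quasi-likelihood adjusted p of 0.291, which did not pass. DESeq2 called this gene, with adjusted p = 0.0373, and the adjusted p ranged from 0.00264 to 1 over all alternative settings. ENSOARG00000003678 had 8.64 ± 0.527 CPM in Low_FEC and 5.41 ± 0.904 CPM in High_FEC lambs (SD, n = 5), a log2 fold change of 0.68 (SE 0.141, edgeR adjusted p = 0.688). DESeq2 called it as well, with adjusted p = 0.0373, over a range of 0.0172 to 1 across settings. Log2 fold changes were 0.33 for ENSOARG00000006293 and -1.27 for ENSOARG00000001778, neither past the threshold. Of 15030 genes tested, edgeR's quasi-likelihood test called 0, and 533 had an unadjusted p under 0.05, where the nominal level gives 751.5. Over 99 other splits of the same libraries the median was 546, from 245 to 1840, so 533 is not a deficit. DESeq2 called 2 genes, limma voom 0, edgeR's likelihood ratio test 1 and edgeR's exact test, added after the data were seen, 6, of which 5 were lower in Low_FEC lambs. The groups did not overlap for 101 genes, and chance gives 119 (0.794% of genes).

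At day 14 the phenotype comparison addresses the later time. ENSOARG00000020373 had the smallest p, with 2.83 ± 0.863 CPM in High_FEC and 0.752 ± 0.542 CPM in Low_FEC lambs (SD, n = 5). Its log2 fold change was -1.98 (SE 0.38, edgeR quasi-likelihood adjusted p = 0.63). DESeq2 called it, with adjusted p = 0.00391, and over all alternatives the adjusted p ranged from 0.00226 to 1. The quasi-likelihood test also called this gene, with adjusted p = 0.0337, when Low_FEC day 14 replicate 3 was left out. ENSOARG00000006611 was at 2.54 ± 0.863 CPM in High_FEC and 0.872 ± 0.583 CPM in Low_FEC lambs (SD, n = 5), with a log2 fold change of -1.62 that did not pass. Among genes with the higher mean in Low_FEC lambs, ENSOARG00000015903 had a log2 fold change of 0.31 and ENSOARG00000007537 one of 0.33, and neither passed. The edgeR quasi-likelihood test called 0 of 15030 genes, with 535 at an unadjusted p under 0.05. DESeq2 called 1, limma voom 0, edgeR's likelihood ratio test 1 and edgeR's exact test 2. Groups did not overlap for 76 genes, against 119 expected by chance.

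The change from day 7 to day 14 in High_FEC lambs addresses the timing of the response in the more susceptible animals. ENSOARG00000013782 fell from 3.14 ± 1.46 CPM to 0.00577 ± 0.0129 CPM (SD, n = 5), a log2 fold change of -7.38 (edgeR quasi-likelihood adjusted p = 2.41e-05). Every High_FEC library at day 14 lay below every High_FEC library at day 7. The counts behind these values were 24 to 79 per library at day 7, 265 in all. At day 14 there was 1 count over the 5 libraries. Scaled by total counts, day 7 was 236 times day 14, with a 95% counting interval from 42 to 9361. The fitted fold change depends on the prior count because the later group is near 0, so no SE is given for contrasts of this gene with day 14, and counting intervals cover counting error only. This gene was the 1 called of 15030 tested, and 873 genes had an unadjusted p under 0.05. limma voom called 1 gene, edgeR's likelihood ratio test 1 and edgeR's exact test 2. DESeq2 called 2 genes, adding ENSOARG00000003179, which had 100.7 ± 7.71 CPM at day 7 and 80.0 ± 5.85 CPM at day 14 (SD, n = 5), a log2 fold change of -0.33 (edgeR adjusted p = 0.313). ENSOARG00000010453 and ENSOARG00000010111 had log2 fold changes of 0.39 and 0.74, and neither passed in the quasi-likelihood test. edgeR's exact test called ENSOARG00000010111 with adjusted p = 0.00539, in a range up to 1 over the alternatives. The groups did not overlap for 163 genes, against 119 expected by chance.

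**Figure D2:**
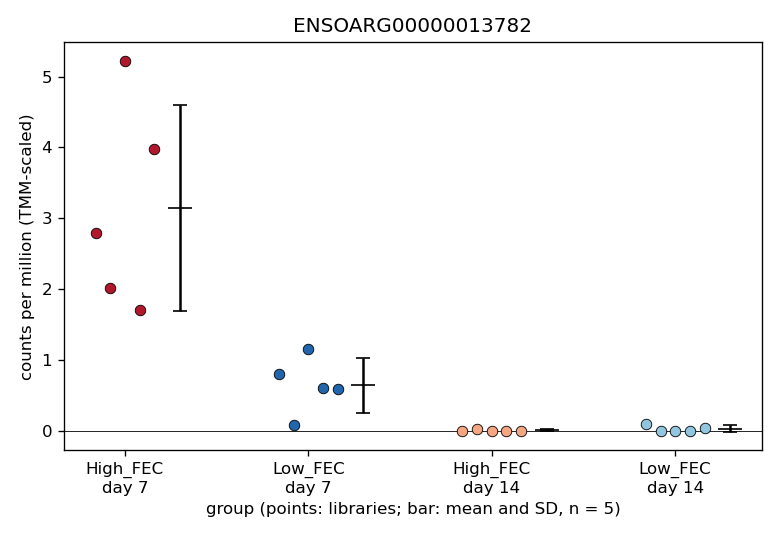
CPM (TMM-scaled) of ENSOARG00000013782 in each of the 20 libraries, by phenotype and day; points are libraries and bars are the group mean and SD (n = 5). High_FEC libraries at day 7 lie between 1.71 and 5.22 CPM, Low_FEC libraries at day 7 between 0.0784 and 1.15 CPM, and no day 14 library holds more than 1 count.

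In Low_FEC lambs the same time comparison gave no call by the quasi-likelihood test. ENSOARG00000013782 again had the smallest p, with 0.643 ± 0.387 CPM at day 7 and 0.0299 ± 0.0455 CPM at day 14 (SD, n = 5). There were 82 counts over the 5 libraries at day 7 and 2 at day 14, a ratio of 25 with a 95% counting interval from 6.69 to 210. The log2 fold change was -4.27 and the edgeR quasi-likelihood adjusted p 0.231. Low_FEC day 7 replicate 2 held 1 count of this gene, and without that library the adjusted p was 0.0168, within a range of 0.000359 to 0.999 over the alternatives. ENSOARG00000011675 had a log2 fold change of 0.40, ENSOARG00000003597 of 0.30 and ENSOARG00000001747 of -0.34, and none passed. The edgeR quasi-likelihood test called 0 of 15030 genes, with 682 at an unadjusted p under 0.05. DESeq2 called 0, limma voom 0, edgeR's likelihood ratio test 1 and edgeR's exact test 2. The exact test used these 10 libraries alone, where ENSOARG00000013782 did not pass the filter, so its 2 calls were of other genes. Groups did not overlap for 119 genes, as many as chance gives.

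The interaction tested whether the time change differed between the phenotypes. For ENSOARG00000013782 the difference of the log2 changes was 3.12 (edgeR quasi-likelihood adjusted p = 1), so the time change was not shown to differ between the phenotypes. At day 14 that gene had 1 count in High_FEC and 2 counts in Low_FEC lambs, over 5 libraries each. The difference therefore depends on the prior count, and the test could not settle whether the phenotypes differ. The genes with the smallest p were ENSOARG00000004031, with a difference of -0.32, and ENSOARG00000013272, with -0.39, and neither passed. ENSOARG00000013272 had 1451 ± 152.4 and 1657 ± 71.2 CPM in High_FEC lambs at days 7 and 14, and 1633 ± 133.5 and 1426 ± 48.1 CPM in Low_FEC lambs (SD, n = 5). Among differences above 0, ENSOARG00000007537 had 0.45 and ENSOARG00000020068 had 0.74, and neither passed. The test called 0 genes, with 542 at an unadjusted p under 0.05, and DESeq2, limma voom and edgeR's likelihood ratio test called 0 each.

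Averaged over the phenotypes, with 10 libraries at each day, ENSOARG00000013782 fell by 5.82 on the log2 scale from day 7 to day 14 (edgeR quasi-likelihood adjusted p = 5.97e-06). It had 347 counts over the 10 libraries at day 7, with at least 1 in each, and 3 counts at day 14, where 7 of 10 libraries had none. ENSOARG00000003179 had the next smallest p, a log2 change of -0.26 with adjusted p = 0.0981, and DESeq2, limma voom and edgeR's likelihood ratio test each called it, with adjusted p of 0.00056, 0.0268 and 0.00658 in a range up to 0.266. ENSOARG00000017888 had a log2 change of 0.28 and ENSOARG00000010111 of 0.52, and neither passed. DESeq2 called ENSOARG00000017888, with adjusted p = 0.0186 in a range up to 0.687, and the quasi-likelihood test did so without High_FEC day 14 replicate 4, with adjusted p = 0.0293. The quasi-likelihood test called 1 gene, with 1015 at an unadjusted p under 0.05. DESeq2 called 6 genes, limma voom 2 and edgeR's likelihood ratio test 4. Among these, ENSOARG00000010231, named after its values were seen, had a log2 change of -2.29 in DESeq2 (adjusted p = 0.00133) and in the likelihood ratio test (adjusted p = 0.00192). Its quasi-likelihood adjusted p was 0.363, and 0.0212 without High_FEC day 7 replicate 3, where the log2 change was -1.52. Averaged over days, the Low_FEC minus High_FEC contrast had its smallest p at ENSOARG00000020373, with a log2 fold change of -1.31 (SE 0.253, edgeR adjusted p = 0.665). ENSOARG00000016502 had -0.90, ENSOARG00000002320 had 0.59 and ENSOARG00000003678 had 0.38, and none passed. The quasi-likelihood test called 0 genes, with 532 at an unadjusted p under 0.05, DESeq2 called 1, limma voom 0 and edgeR's likelihood ratio test 1.

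**Figure D3:**
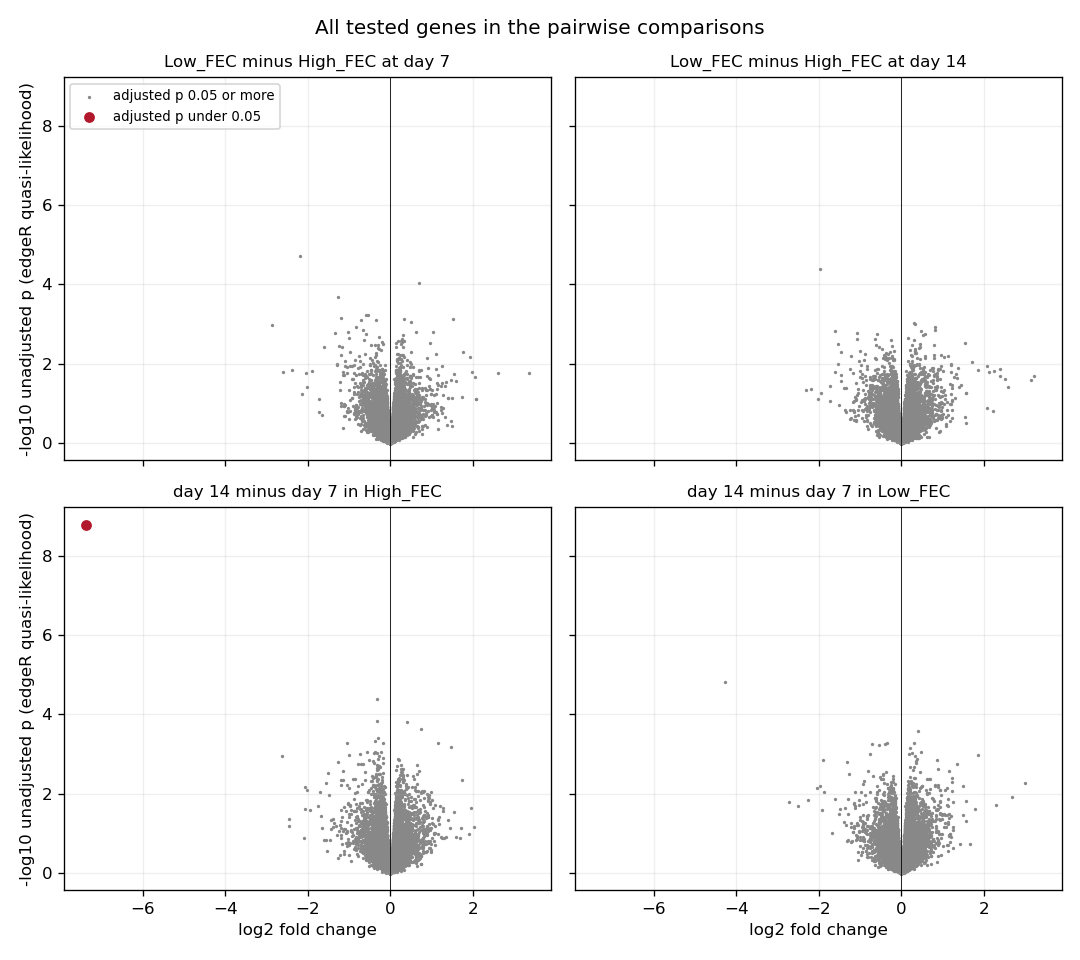
Log2 fold change (x axis) and -log10 unadjusted p from edgeR's quasi-likelihood test (y axis) for the 15030 tested genes in the 4 pairwise comparisons; red marks an adjusted p under 0.05. The 1 red point is ENSOARG00000013782 in the day comparison of High_FEC lambs, at a log2 fold change of -7.38.

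The precision of these comparisons limits how large a missed change could be. The 95% confidence interval of the fold change lay within 2-fold in either direction for 90.4% of tested genes in the day 7 phenotype comparison, 89.3% at day 14, 89.3% for time in High_FEC and 89.8% for time in Low_FEC lambs. Among the 9896 genes above 10 CPM these shares were 98.3%, 98.5%, 98.4% and 98.3%. Among the same abundant genes, 93.9%, 93.3%, 93.4% and 93.7% had an interval within 1.5-fold. For the interaction the interval lay within 2-fold for 80.1% and within 1.5-fold for 60.6% of tested genes, and within 1.5-fold for 84.7% of the genes above 10 CPM. In simulated counts for the 15030 genes with 50 genes changed 2-fold, the quasi-likelihood test recovered 74% in the day 7 phenotype comparison, 82% at day 14, 90% for time in High_FEC and 74% for time in Low_FEC lambs. At 1.5-fold it recovered 78%, 52%, 46% and 52% of 50 genes. Each share comes from 1 draw of 50 genes of its own, without a sampling error. Of the genes changed 1.5-fold, 38, 34, 29 and 26 lay above 10 CPM, so the draws were not of like abundance. Differences between these shares, such as 78% at 1.5-fold and 74% at 2-fold for day 7, are therefore not differences in power. Each simulation changed 200 genes at once, which eases the adjusted threshold, so these shares do not hold where few genes change. They also leave out correlation between genes, since each gene was drawn independently.

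Across the 15030 tested genes, which are not independent replicates, the time changes in High_FEC and Low_FEC lambs had a Pearson correlation of 0.145 and a Spearman correlation of 0.122, and 55% of genes had the same sign. These comparisons share no library. Of 100 labellings of day within phenotype, the real one included, 4 gave a Pearson correlation as large and 11 a Spearman correlation as large (one-sided). ENSOARG00000013782 was among the genes, with log2 changes of -7.38 and -4.27, where the SD over all genes was 0.2385 and 0.2269. Changes of that size weigh heavily in a Pearson correlation, and no value without this gene was computed. The Pearson share therefore does not by itself show a time change shared over many genes. The Pearson correlation was 0.0689 without Low_FEC day 7 replicate 3, and it no longer passed in 15 of 20 fits that left out 1 library. The phenotype differences at day 7 and day 14 had a Pearson correlation of 0.0811 and a Spearman correlation of 0.0298, with 50.2% of genes of the same sign. Of 100 labellings of phenotype within day, 19 gave a Pearson and 40 a Spearman correlation as large.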

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

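The test of the most abundant gene against phenotype and day and the count of genes whose days do not overlap were chosen after values were seen. The tests of library depth, of genes that accompany ENSOARG00000013782 and of the share of reads outside genes were set out before their results were computed. Single libraries were tested for standing far from the other 4 of their group in 104 sets of 5 values, where chance gives about 1 in 20, or 5.2, and 7 stood apart.

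ENSOARG00000013782 had 347 counts over the 10 libraries at day 7, of which Low_FEC day 7 replicate 2 held 1, and 3 counts over the 10 libraries at day 14. Shallower libraries at day 14 do not account for the loss, since at the mean day 7 level the day 14 libraries would hold 289 counts and they held 3. Reads of other cells or another organism in the day 7 libraries should bring further genes along if they fall in many genes. Over those 10 libraries 2 genes correlated with ENSOARG00000013782 above 0.9, against a median of 3 for 200 genes of similar abundance. A cell type with few abundant transcripts stays open. So does another organism whose reads fall in few of the tested genes, since this count cannot show either. A library batch shared by the samples of one day could move many genes, and 1 gene had days that did not overlap, where chance gives 0.16. That gene was not ENSOARG00000013782, whose own days overlapped. This count sees only shifts larger than the whole spread within a day, so it cannot exclude a smaller batch shift in many genes. The labels used here name no batch, and one that follows the day cannot be told apart from the day, whether it acts on ENSOARG00000013782 alone or on more genes. A transcript higher in the node at day 7 than at day 14 is a hypothesis that may fit these counts, and it was found and tested on the same libraries.

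ENSOARG00000009143, the most abundant gene on average, ranged from 3664 to 28909 CPM over the 20 libraries, 7.89-fold. Low_FEC day 14 replicate 1 stood apart with 28909 CPM, the other 4 libraries of its group lying between 3938 and 8547, and with 8.14% of its counts in the 10 most abundant genes, against 3.55% to 4.60%. The level did not follow phenotype or day in exact permutation tests (smallest adjusted p = 0.73 over 4 comparisons), and the correlation with library depth did not pass (Pearson r = 0.35, permutation p = 0.13, Spearman rho = 0.411, permutation p = 0.073, r = 0.276 without the 2 libraries of most extreme depth). It fell with the share of reads outside genes over the 20 libraries (Pearson r = -0.485, permutation p = 0.031, Spearman rho = -0.544, permutation p = 0.014, r = -0.489 without the 2 most extreme libraries). Adjusted over the 2 relations, the permutation p was 0.062 for Pearson and 0.028 for Spearman, and 30 other tested genes followed the gene at r above 0.9 over the 20 libraries. Reads of these genes are part of the total behind the share outside genes, so part of this negative relation can be built in. The composition of the RNA in each piece of node may be involved, which was not tested further.

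High_FEC day 14 replicate 2 had 34710314 counts in genes, against 9024996 to 15552250 in the other 4 libraries of its group. High_FEC day 7 replicate 4 had 0.802% ambiguous reads, against 0.684% to 0.704%. ENSOARG00000010111 was at 13.2 CPM in High_FEC day 7 replicate 3, against 8.06 to 8.56 in its group. ENSOARG00000011675 was at 184.1 CPM in High_FEC day 7 replicate 4, against 212.7 to 223.6. Reads counted in no gene, which no comparison of genes used, made up a median of 44.25% of each library. For ENSOARG00000013782, High_FEC day 14 replicate 2, the deepest library, stood apart with 0.0288 CPM, which is the 1 count of its group.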

How the results depend on the processing

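edgeR's exact test was chosen after the data were seen, and the other alternatives before. The fall of ENSOARG00000013782 in High_FEC lambs passed under every alternative run (log2 fold change -8.73 to -6.08, adjusted p 9.01e-22 to 0.00349). Counts of calls by the quasi-likelihood test kept within 1.5 times under RLE scaling, no filter, the stricter filter, without the 20 most abundant genes and, for pairwise comparisons, on the 10 libraries alone. RLE scaling moved the median log2 change of all genes by between -0.0031 and -0.00058, and no gene named here changed direction. DESeq2 called 2 genes for phenotype at day 7, 1 at day 14, 2 for time in High_FEC lambs, 1 for phenotype averaged and 6 for time averaged. The likelihood ratio test called 1 for phenotype at day 7, 1 at day 14, 1 for time in Low_FEC lambs, 1 for phenotype averaged and 4 for time averaged. edgeR's exact test called 6 for phenotype at day 7, 2 at day 14, 2 for time in High_FEC and 2 in Low_FEC lambs. For time averaged, voom called 2 and an adjusted p threshold of 0.1 gave 2. The cause of these differences was not tested. Leaving out 1 library in turn gave 0 to 1 calls for phenotype at day 14, with 1 without Low_FEC day 14 replicate 3, and 0 to 1 for time in Low_FEC lambs, with 1 without Low_FEC day 7 replicate 2 and 1 without Low_FEC day 14 replicate 3. It gave 0 to 1 for phenotype averaged, with 1 without Low_FEC day 14 replicate 3, and 1 to 3 for time averaged. There, 3 genes were called without High_FEC day 14 replicate 4, and 2 without each of Low_FEC day 7 replicate 4, High_FEC day 7 replicate 3 and High_FEC day 7 replicate 4. The Pearson correlation of 0.145 between the time changes did not pass as the Spearman correlation of 0.122, and ranged from 0.0689, without Low_FEC day 7 replicate 3, to 0.19, without Low_FEC day 7 replicate 4. It was 0.0709 without Low_FEC day 7 replicate 1, 0.0809 without Low_FEC day 14 replicate 1 and 0.0888 without Low_FEC day 14 replicate 2. Against the labellings of all 20 libraries it no longer passed in 15 of 20 such fits, and is a borderline value. In Low_FEC lambs ENSOARG00000013782 did not pass the filter when those 10 libraries were fitted alone. Low_FEC day 7 replicate 2 held 1 count of it, and the Low_FEC day 14 libraries held 2 in all. The gene list tests and their alternatives were not run, because the identifiers were not paired with symbols here, and the tests of lists have no value. No paired analysis was possible because the labels give no replicate numbers and different lambs were sampled at each day.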

Other observations

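The shuffle test of shared splits, the Fisher tests of genes with 2 levels and the counts of splits for genes called were chosen after the values were seen, and the other tests in this part before. Of the 15030 tested genes, 22 had 2 separate levels, with a gap of at least 4-fold between sets of at least 3 libraries each. The rule finds a gap in level and not absence: ENSOARG00000016098 still averaged 52.6 CPM in its lower set. ENSOARG00000008077 lay at 66.5 CPM or above in 9 libraries and at most at 1.65 CPM in the other 11. ENSOARG00000009526 lay at 10.2 CPM or above in the same 9 libraries and at most at 0.728 CPM in the other 11. These libraries came from all 4 groups: 2 of 5 High_FEC and 2 of 5 Low_FEC at day 7, and 2 of 5 High_FEC and 3 of 5 Low_FEC at day 14. Another pair of genes lay at most at 0.525 CPM in the same 3 day 14 libraries and at 3.08 CPM or above in the other 17. The 3 libraries were Low_FEC day 14 replicates 2 and 3 and High_FEC day 14 replicate 1, which follow one another in the order of deposit. The labels used here do not say whether that order reflects how the samples were handled or how the lambs were related.

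Chance agreement of independent splits was tested by shuffling the libraries of each of the 22 genes 1000 times: the genes formed 2 pairs with the same or the mirror split, and no shuffle gave more than 1. Library depth would not account for the pattern, since 17 of the 22 genes would hold over 30 counts in the shallowest library of their lower set at the mean level of their higher set. The splits did not follow phenotype or day past the threshold (smallest Fisher exact p 0.00548, adjusted p = 0.219 over 40 tests). That smallest p belonged to ENSOARG00000011082, which lay at 11.9 CPM or above in 9 of 10 High_FEC and 2 of 10 Low_FEC libraries and at most at 1.64 CPM in the others. A candidate explanation for single genes among the 22 is a difference between lambs in the gene itself, such as a variant against the reference. Whether it could also account for the 2 pairs of genes that shared a split cannot be told, since no positions of the genes were used. Neither the candidate nor the cause of the shared splits was tested.

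The hypothesis that the groups differ by small differences spread over many genes was tested on the distances between libraries, as the ratio of mean squared distance between and within groups over all 126 splits of the 10 libraries. For phenotype, 82 splits at day 7 and 86 at day 14 gave a ratio as large as the real one. For time, 28 splits in High_FEC and 95 in Low_FEC lambs did, so no such difference was detectable in any of the 4 comparisons.

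The number of genes called was set against 100 splits of the same libraries for each contrast, the real one included. A real count of 0 is reached by all 100 splits by construction and says nothing about chance. This holds for phenotype at day 7, at day 14 and averaged, the interaction, and time in Low_FEC lambs, where the highest other splits called 1, 3, 4, 2 and 119 genes. For time in High_FEC lambs 14 of 100 splits called as many as the real 1 gene, the highest other being 3, and for time averaged 6 of 100 did, the highest other being 34, so chance could not be excluded for these 2 counts. The splits that called 34 and 119 genes may reflect a structure among some libraries or chance with correlated genes, and no test here separates these; 10 or more genes were called in 1 of 99 other splits for time averaged and 2 of 99 for time in Low_FEC lambs. A count of calls says nothing of the size of the change, and the splits did not test the 1 gene that fell.

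For genes at an unadjusted p under 0.05, 52 of 100 splits reached the real 533 for phenotype at day 7 (highest other 1840), 87 the real 535 at day 14 (highest other 1786), and 71 the real 532 averaged (highest other 1380). For time, 27 reached the real 873 in High_FEC lambs (highest other 1738), 53 the real 682 in Low_FEC lambs (highest other 2058), and 19 the real 1015 averaged (highest other 1374). For the interaction, 71 reached the real 542 (highest other 1639). Chance could not be excluded for any of these counts.

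For the correlation of the time changes between phenotypes, 4 of 100 labellings gave a Pearson correlation as large as 0.145, the highest other being 0.224, a one-sided share under 0.05 in 1 of 2 correlations tested. As 11 of 100 gave a Spearman correlation as large, and most fits without 1 library did not pass, this result is borderline. The Pearson value also includes ENSOARG00000013782, whose large log2 changes weigh heavily in it, and was not computed without that gene. For the phenotype differences at the 2 days, 19 of 100 gave a correlation as large as 0.0811, the highest other being 0.348, and chance could not be excluded.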
